A study of Mus musculus with 4 samples.

How the data were processed

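RNA was measured in ANA-1 cells, a mouse macrophage line derived from bone marrow and immortalised with a retrovirus. The cells were infected with Chlamydia pneumoniae, an obligate intracellular bacterium of the airways, or mock infected, and total RNA was taken 8 h later with Trizol, per the labels. Each group held 2 biological replicates, named A and B, which gave 4 arrays. Biotin-labelled target was made by a single round of Affymetrix amplification, per the labels' protocols.

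The authors deposited 1 value per probe set and array, an intensity on a linear scale. RMA, the affy package and R 2.4.0 are named in the submitters' processing notes. The version of affy, any filter and the set of arrays processed together are not given in the sources used here. RMA corrects background, makes the arrays' distributions alike and summarises several probes, so a change that shifted most transcripts one way would be reduced in these values. The test had been planned for values already on a log2 scale, and since the deposited intensities were linear, their log2 was taken first. The median intensity per array lay between 87.8 and 91.9. The number of arrays limits the precision, since the values carry no count or detection call.

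Of 12488 probe sets, 66 Affymetrix controls were set aside and 12422 were tested. The platform annotation gave 10833 of these 1 gene symbol, 396 several and 1193 none. The Entrez gene number of 10817 was found in the mouse RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No gene was named from a probe set with several symbols. Where a gene had several probe sets, the one with the highest mean over all 4 arrays stood for it in the gene lists, which gave 8251 genes. Tlr2, Tlr4 and Gapdh had been chosen for naming and had no probe set with a single symbol, so they are not reported here as genes.

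Infected and mock arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block), with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. Every adjusted p below comes from limma. Standard errors are limma's moderated ones, and each change is the mean log2 value of infected arrays minus that of mock arrays. For gene lists, limma's camera was run with a preset inter-gene correlation of 0.01 on 32 lists of at least 4 measured genes, and again with the correlation estimated from the data. Rotation tests (fry) and rank-based camera were alternatives. Members were also counted after adjustment over the list alone.

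The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took up to 15 genes per direction with the largest change among those past the threshold whose infected arrays lay on one side of both mock arrays, and the 5 with the smallest p in a direction where none passed. It also took up to 2 risen and 2 fallen members of each list, or the member with the smallest p where none passed, and a set of genes of macrophage activation with reference genes. Further genes are named where members of a list passed when adjusted over the list alone, and those were chosen after their values were seen.

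The alternatives were the replicate letter as a block, leaving out the dimmest 25% or 50% of probe sets, subtracting array medians, cyclic loess, a further quantile normalization, a trended or robust variance prior, a threshold of 0.01, a 2-fold minimum, a rule without p-values, probe sets without a cross-hybridisation suffix, the mean over a gene's probe sets, and leaving out each array in turn. The tests were checked on simulated arrays with 200 of 12422 probe sets changed, in 20 simulations of 2 against 2 arrays that kept the observed difference between the letters. With equal responses in A and B, 31.2% of changes of 1 on the log2 scale, 94.8% of changes of 2 and 98.9% of changes of 3 passed without the block. With responses that varied between the letters, with an SD of 0.3 of each change, these shares were 0.382%, 32.8% and 40.7%. With the block, 100% of changes of each size passed for equal responses, with 7.42% of calls false on average, above the 5% aimed at. For varying responses the block passed 94.3%, 96.4% and 97.2% of changes of 1, 2 and 3, with 1.29% of calls false. Without the block 0% of calls were false in both. A list shifted by 0.3, tested within the 8251 genes, was called by camera in 100% of simulations. The simulated noise was independent between genes, so this check cannot speak to lists of correlated genes. Its variances were drawn from the fit with the block, and unchanged probe sets had no response that differed between the letters. The simulation therefore favours the block by construction, and its share of false calls may not hold for the real arrays.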

Results

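Transcript levels were measured on 4 arrays of ANA-1 macrophages, 2 from mock-infected and 2 from Chlamydia pneumoniae-infected cultures, 8 h after infection. The design asks which transcripts differ between infected and mock-infected macrophages at that time. Levels are log2 RMA intensities, given as mean ± SD with n = 2 arrays per group. The 2 replicates were described as biological, and no label says what the letters A and B share.

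The transcripts that rose past the threshold in infected cells were Saa3, Cxcl2, Acod1, Ccl3, Nfkbiz, Tnf and Cebpd. Saa3, an acute phase serum amyloid protein made by macrophages, rose 17.6-fold, from 7.27 ± 0.45 to 11.41 ± 0.28. Cxcl2, a chemokine that attracts neutrophils, rose 12.7-fold, from 4.31 ± 0.07 to 7.97 ± 0.31. Acod1, the enzyme that makes itaconate, rose 9.20-fold, and Ccl3, a chemokine for monocytes and lymphocytes, rose 5.31-fold. Nfkbiz, a nuclear regulator of NF-kB target genes, Tnf, and the transcription factor Cebpd rose 4.83-fold, 4.53-fold and 3.76-fold.

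These 7 were the probe sets past the threshold in limma, out of 12422, and in all 7 both infected arrays lay above both mock arrays. The log2 change was 4.14 (SE 0.26, adjusted p = 0.031) for Saa3, 3.66 (SE 0.18, adjusted p = 0.031) for Cxcl2 and 3.20 (SE 0.18, adjusted p = 0.031) for Acod1. It was 2.41 (SE 0.14) for Ccl3 and 2.27 (SE 0.14) for Nfkbiz, with the same adjusted p of 0.031, 2.18 (SE 0.15, adjusted p = 0.037) for Tnf and 1.91 (SE 0.14, adjusted p = 0.043) for Cebpd. Within replicate A and replicate B taken singly, Saa3 was higher by 3.63 and 4.65, Cxcl2 by 3.93 and 3.39, Acod1 by 3.44 and 2.97, Ccl3 by 2.55 and 2.27, Nfkbiz by 2.44 and 2.10, Tnf by 2.002 and 2.356, and Cebpd by 1.84 and 1.98. A second Acod1 probe set gave 1.08, and the mean over the probe sets of Nfkbiz gave 1.32 with an adjusted p of 0.063. Without infected replicate A or without infected replicate B, limma called 0 probe sets, while without mock replicate A it called 8 and without mock replicate B 6. Cyclic loess left 3 calls and a further quantile normalization left 0, with the 7 changes still positive under both. With the replicate letter as a block 699 probe sets passed, 540 higher and 159 lower, in a fit with 1 residual degree of freedom.

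**Figure D1:**
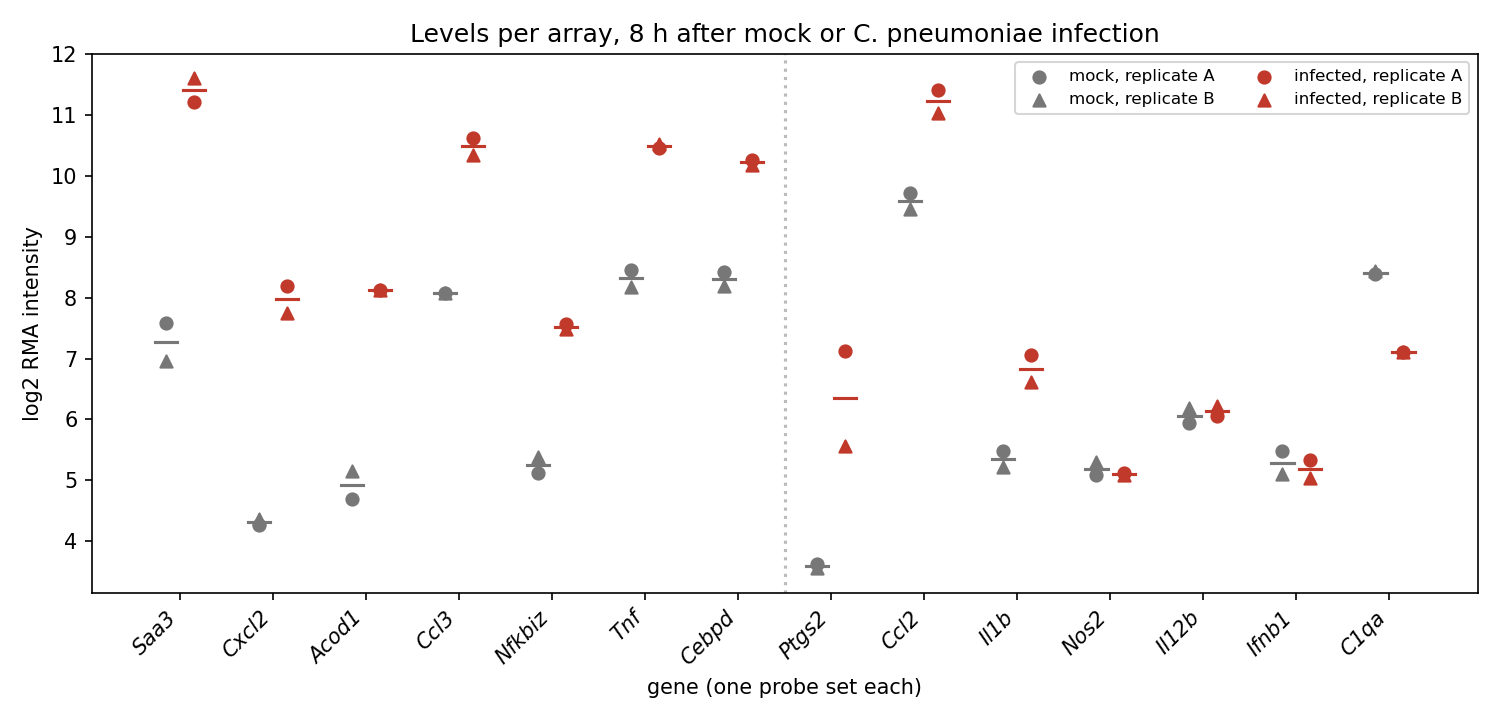
Level of 14 genes on each array, as log2 RMA intensity, with circles for replicate A, triangles for replicate B and a short line at the mean of each group (n = 2). The 7 genes left of the dotted line passed the limma threshold, Saa3 going from 7.27 to 11.41, and the 7 genes right of it did not.

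No probe set passed as lower in infected cells, where limma gave 0 calls and 58 probe sets lay lower at an unadjusted p under 0.05. The 5 genes with the smallest p in that direction all fail the correction in this fit, which has no block. With the replicate letter as a block these 5 passed. C1qa, a subunit of the first component of complement, was at 8.41 ± 0.03 in mock and 7.11 ± 0.00 in infected arrays, a difference of -1.30 (SE 0.12, adjusted p = 0.10). Differences were -0.89 for Ahnak (adjusted p = 0.26), -1.01 for Cytip (adjusted p = 0.42), -0.65 for Ctla2b (adjusted p = 0.68) and -0.81 for C1qc (adjusted p = 0.86), each with both infected arrays below both mock arrays. With the mean over a gene's probe sets as 1 value per gene, C1qa passed (adjusted p = 0.041). At the unadjusted threshold 330 probe sets lay past in all, 272 of them higher, against 621 that no effect would give on independent arrays. A rule without p-values, at least 2-fold and no overlap between the groups' arrays, took 48 higher and 2 lower probe sets. Of all probe sets 25.2% had separated groups, and chance gives 33.3% on independent arrays. Arrays of the same letter deviated together (correlation 0.763 across probe sets), so neither expectation holds exactly here.

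Several genes known from macrophage activation were higher in both infected arrays and did not pass in this fit, which has no block. Ptgs2, the inducible cyclooxygenase, differed by 2.75 (SE 0.50, adjusted p = 0.49), with 3.50 in replicate A and 2.01 in replicate B. Differences were 1.64 for Ccl2, 1.49 for Il1b, 1.08 for Nfkbia, 0.87 for Il6, 0.77 for Socs3, 0.47 for Ccl5, 0.37 for Ifit1 and 0.37 for Cxcl10, with an adjusted p of 0.16 or more. In replicate A and replicate B taken singly these were 1.32 and 0.42 for Il6, 0.68 and 0.27 for Ccl5, 0.68 and 0.07 for Ifit1 and 0.64 and 0.11 for Cxcl10. Il6 was dim, at 3.05 in mock and 3.92 in infected arrays, where the brightest yeast control averaged 3.87. Ifit1 and Cxcl10 lay at 4.57 and 4.45 in infected arrays, below the median of 5.80 for markers of lymphoid, erythroid and endothelial cells. For these 3 genes background may hide or blur a change. Without infected replicate A the differences were 0.41 for Il6, 0.19 for Ifit1 and 0.11 for Cxcl10, and without infected replicate B 1.33, 0.56 and 0.64. Nos2, the inducible nitric oxide synthase, differed by -0.09, Il12b by 0.08, Ifnb1 by -0.10, Il10 by -0.08, Irf1 by -0.01 and Myd88 by 0.09, all with overlapping groups. With 1 array left out Il10 ranged from -0.16 to -0.0075 and Myd88 from 0.016 to 0.17. The reference genes Actb and Hprt differed by 0.03 and 0.28, and that of Actb turned to -0.02 with cyclic loess.

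Among the lists fixed before the data were examined, those of NF-kB signalling, chemokines, antimicrobial effectors and cytokines were each higher in infected cells. With the preset correlation, camera compares a list's genes with all other genes, so its p here and below does not measure the spread between cultures. Camera placed the NF-kB pathway list higher (mean change 0.60 over 21 genes, adjusted p = 2.61e-16 with the preset correlation, adjusted p = 0.44 with an estimated correlation). Nfkbiz was its 1 member past the threshold over all probe sets, and 11 members passed as higher and 0 as lower when adjusted over the list alone, among them Ikbke at 1.35, Nfkbia at 1.08 and Tnip1 at 0.81. The chemokines were higher (mean 0.66 over 20 genes, adjusted p = 1.97e-05, adjusted p = 0.51 with an estimated correlation). Cxcl2 and Ccl3 passed over all probe sets, and adjusted over the list alone Ccl7 at 2.66, Ccl4 at 2.03 and Ccl2 at 1.64 passed too. The median over the 20 was 0.07, and rank-based camera gave an adjusted p of 0.28. Antimicrobial and inflammatory effectors were higher (mean 0.63 over 28 genes, adjusted p = 8.41e-12, adjusted p = 0.44 with an estimated correlation). Saa3 and Acod1 passed over all probe sets and 8 members when adjusted over the list alone, with Ptgs2 at 2.75, the scavenger receptor Marco at 1.22 and the protease inhibitor Slpi at 1.10. Cytokines were higher (mean 0.31 over 22 genes, adjusted p = 0.0030, adjusted p = 0.51 with an estimated correlation). Tnf passed over all probe sets, and Il1b at 1.49, the interleukin-1 receptor antagonist Il1rn at 1.10 and Ebi3 at 0.76 when adjusted over the list alone. The median of the cytokines was 0.03, and rank-based camera gave an adjusted p of 0.24.

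Lists of stress and of early transcription factors were higher as well. Oxidative stress and metal response genes had a mean change of 0.30 over 19 genes (adjusted p = 5.85e-06, adjusted p = 0.44 with an estimated correlation), and adjusted over the list alone Sod2 at 1.41, Gsr at 0.93, Hmox1 at 0.54 and Txnrd1 at 0.51 passed, with 0 members past over all probe sets. Immediate early and stress-induced transcription factors had a mean of 0.25 over 22 genes (adjusted p = 4.54e-04, adjusted p = 0.51 with an estimated correlation). Cebpd passed over all probe sets, and Ets2 at 0.91 and Cebpb at 0.68 when adjusted over the list alone. The unfolded protein and amino acid starvation list had a mean of 0.31 over 23 genes (adjusted p = 1.95e-06, adjusted p = 0.51 with an estimated correlation), where 0 members passed by either count and Herpud1, a factor of protein disposal at the endoplasmic reticulum, was at 1.15. Glycolysis and hypoxia genes had a mean of 0.25 over 19 genes (adjusted p = 3.18e-04, adjusted p = 0.60 with an estimated correlation), and the glucose transporter Slc2a1 was at 0.86. Heat shock proteins had a mean of 0.17 over 15 genes (adjusted p = 0.012, adjusted p = 0.60 with an estimated correlation), with Hspa8 at 0.38. These last 3 lists also lay higher in replicate B than in replicate A, by 0.35, 0.34 and 0.24.

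The 2 interferon lists were tested singly. The type I interferon response list was higher (mean 0.27 over 25 genes, adjusted p = 2.33e-08, adjusted p = 0.51 with an estimated correlation). None of its genes passed by limma over all probe sets or when adjusted over the list alone, and Rsad2, an antiviral enzyme, was at 0.57. Of the 25 genes, 14 lay above both mock arrays and 1 below both. Chance separates 33.3% on independent arrays, and 25.2% of all probe sets were separated. The mean of the list was 0.39 within replicate A and 0.15 within replicate B. Interferon-inducible GTPases and interferon-gamma targets had a mean of 0.00 over 13 genes (adjusted p = 0.80), with Gbp7 at 0.25, which was 0.48 in replicate A and 0.02 in replicate B, and 0.05 to 0.45 with 1 array left out. The difference between these lists was not tested.

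Pattern recognition receptors had a mean change of 0.20 over 11 genes (adjusted p = 0.035, adjusted p = 0.51 with an estimated correlation), with the C-type lectin Clec4e at 0.85 past when adjusted over the list alone. Costimulation, adhesion and activation markers had a mean of 0.20 over 19 genes (adjusted p = 0.044, adjusted p = 0.60 with an estimated correlation), with the adhesion molecule Icam1 at 0.95. Camera called the macrophage identity list lower (mean -0.07 over 22 genes, adjusted p = 0.038, adjusted p = 0.51 with an estimated correlation). C1qa was its 1 member past when adjusted over the list alone. Rank-based camera ended the calls of these 3 lists, with adjusted p of 0.16, 0.20 and 0.24. In a comparison chosen after the result was seen, the 3 C1q genes of the identity list had a median change of -0.81. The 19 other identity genes had a median of -0.05 (bootstrap interval over genes, not arrays, -0.14 to 0.17). The call therefore does not show a fall of identity genes other than C1q. Camera also called markers of natural killer cells lower (mean -0.14 over 7 genes, adjusted p = 0.026). It called those of fibroblasts lower too (mean -0.11 over 14 genes, adjusted p = 0.041). With an estimated correlation each list had an adjusted p of 0.60. ANA-1 is a macrophage line, so these calls do not show a change in such cells. Cyclic loess ended both calls, at means of -0.12 and -0.10. Gzma was at -0.18 in the natural killer list and Thy1 at -0.30 in the fibroblast list, and with 1 array left out they ranged from -0.36 to -0.0077 and from -0.48 to -0.12.

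In all, camera with the preset correlation called 15 of 32 lists, 12 higher and 3 lower, while 0 passed with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.0902. Both of these tests rest on the 2 residual degrees of freedom of the fit. The smallest unadjusted p of camera with an estimated correlation was 0.0147, before correction over 32 lists. With so few arrays, 0 calls cannot show that the lists did not change. With each array left out in turn, 6 of the 15 kept their call every time, namely the NF-kB, chemokine, antimicrobial, type I interferon, unfolded protein and oxidative stress lists. The unfolded protein mean of 0.31 was 0.11 without infected replicate B, 0.17 without mock replicate A and 0.51 without infected replicate A. The other 9 lost it at least once. Calls ended without mock replicate A for glycolysis (mean 0.08), heat shock (0.06), costimulation (0.07), natural killer (-0.09), fibroblast (-0.06) and macrophage identity genes (-0.14). Without infected replicate B they ended for glycolysis (0.09), heat shock (0.04), costimulation (0.13), pattern recognition (0.17), natural killer (-0.04) and fibroblast genes (0.0063). Without mock replicate B they ended for cytokines (0.29), pattern recognition (0.23), early transcription factors (0.19) and macrophage identity genes (0.0039), and without infected replicate A for cytokines (0.23), early transcription factors (0.17) and macrophage identity genes (-0.03). Means also moved by over 1.5 times with the call kept. Without infected replicate A glycolysis was at 0.42, heat shock at 0.30, natural killer at -0.24 and fibroblast genes at -0.22, without mock replicate B glycolysis was at 0.43, heat shock at 0.27 and costimulation at 0.33, and without infected replicate B macrophage identity genes were at -0.10.

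**Figure D2:**
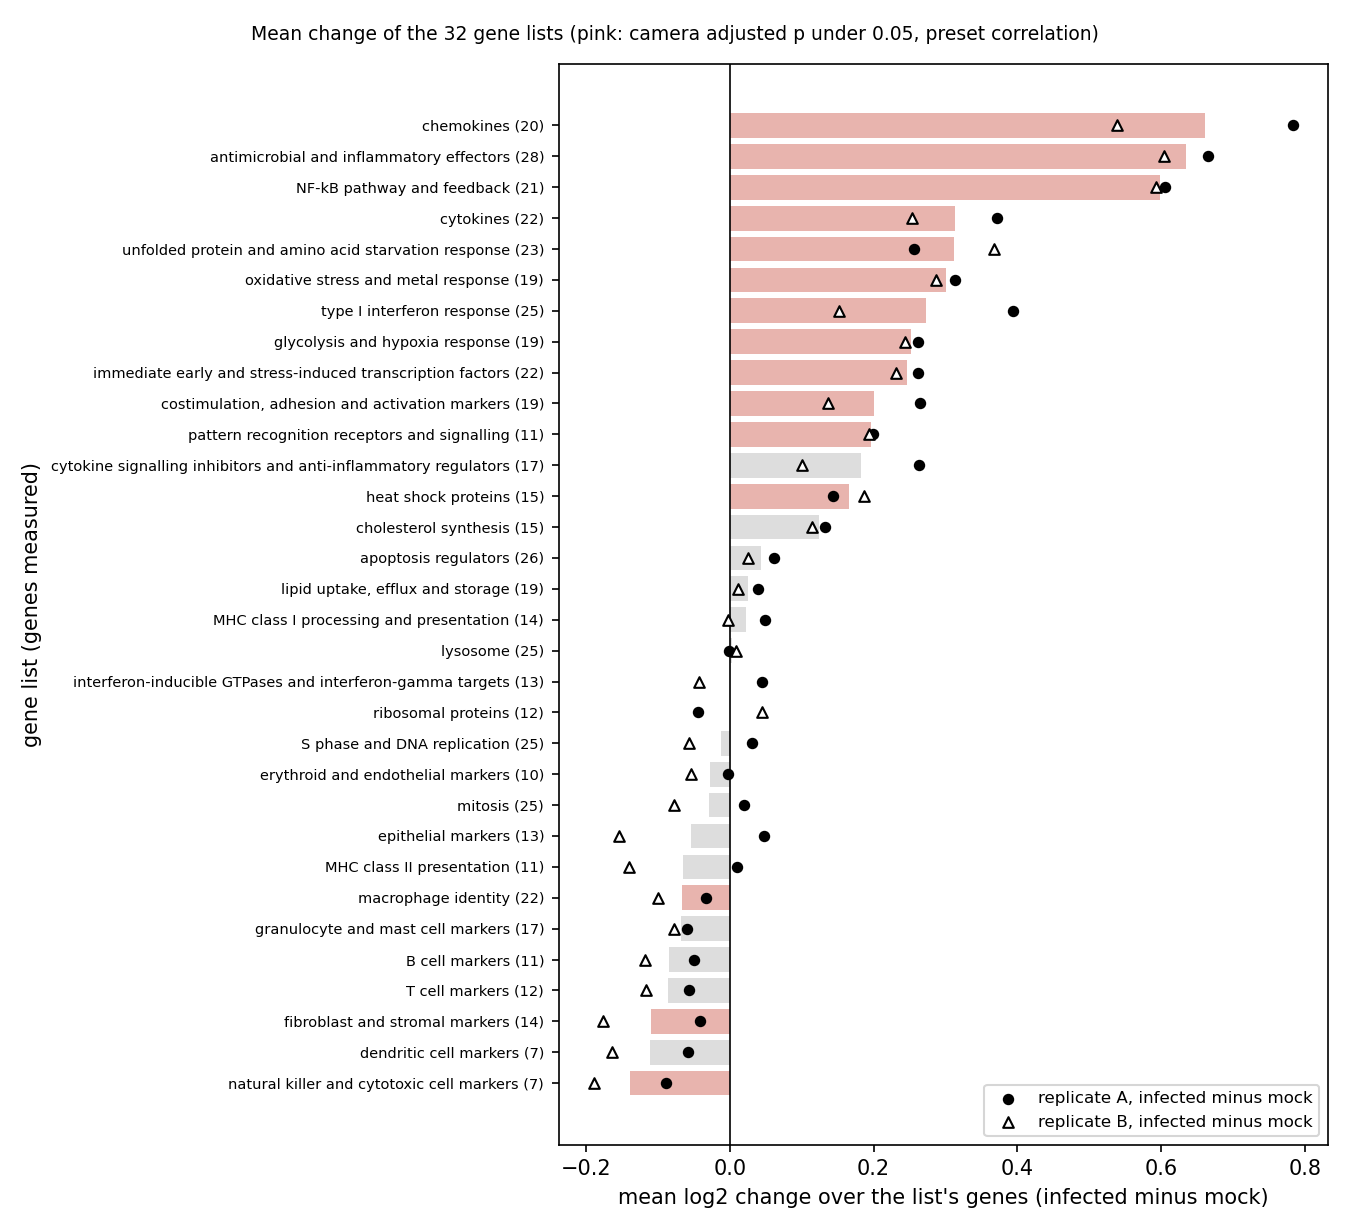
Mean log2 change, infected minus mock, of the 32 gene lists, with the number of genes measured in brackets, bars for the mean over all 4 arrays and symbols for replicate A (filled circle) and replicate B (open triangle). Chemokines, antimicrobial effectors and the NF-kB pathway lie at 0.66, 0.63 and 0.60, and pink bars mark adjusted p under 0.05 with the preset correlation, none of which held with an estimated one.

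The remaining lists did not pass. Inhibitors of cytokine signalling had a mean of 0.18 over 17 genes (adjusted p = 0.10), and adjusted over the list alone Tnfrsf1b at 1.27, Atf3 at 1.03 and Socs3 at 0.77 passed as higher and the decoy receptor Il1r2 at -0.63 as lower. The Atf3 probe set carries the f suffix, and the mean over the probe sets of Atf3 gave 0.58. Apoptosis regulators had a mean of 0.04 over 26 genes (adjusted p = 0.80), with Fas at 0.70 and Casp4 at 0.67 past when adjusted over the list alone. Fas was dim, at 3.44 in mock and 4.14 in infected arrays, where the brightest yeast control averaged 3.87. Cholesterol synthesis had a mean of 0.12 (adjusted p = 0.24, Hsd17b7 at 0.28), lipid uptake and storage 0.03 (adjusted p = 0.90, Lpl at 0.51) and lysosome 0.00 (adjusted p = 0.69, Ctsc at 0.41). MHC class I genes had a mean of 0.02 (adjusted p = 0.90, Tap1 at 0.26) and MHC class II genes of -0.07 (adjusted p = 0.21, H2-Oa at -0.16). S phase genes had a mean of -0.01 (adjusted p = 0.57, Tk1 at -0.29), mitosis genes of -0.03 (adjusted p = 0.35, Cdc25c at -0.17) and ribosomal protein genes of 0.00 (adjusted p = 0.80, Rpl7 at 0.14). With 1 array left out the MHC class II mean ranged from -0.11 to -0.019, Tap1 from 0.07 to 0.44, Ctsc from 0.25 to 0.57 and Cdc25c from -0.27 to -0.07, and as the mean over a gene's probe sets Tap1 was at 0.06, Ctsc at 0.27, Cdc25c at -0.07 and Tk1 at -0.18. For MHC class I, lipid and lysosome genes the mean was above 0 and the median and camera's direction below it, and the same held for ribosomal proteins. Leaving out 1 array brought some of these lists past the threshold. Lysosome genes were at -0.15 without mock replicate A and -0.16 without infected replicate B, mitosis genes at -0.18 and -0.13 there, and inhibitors of cytokine signalling at 0.14 and 0.22. The latter also passed with the mean over a gene's probe sets (0.18). Cholesterol synthesis was at 0.31 without mock replicate B and 0.30 without infected replicate A, and granulocyte markers were at -0.16 and -0.17 there. Markers of other cells had means of -0.11 for dendritic cells (Batf3 at -0.20), -0.09 for T cells (Cd4 at -0.19), -0.08 for B cells (Cd79a at -0.30), -0.07 for granulocytes and mast cells (Camp at -0.27), -0.05 for epithelium (Cldn7 at -0.20) and -0.03 for erythroid and endothelial cells (Vwf at -0.18), with adjusted p between 0.077 and 0.49. With 1 array left out the epithelial mean ranged from -0.11 to 0.00096, the B cell mean from -0.13 to -0.044 (-0.05 as the mean over a gene's probe sets), Cldn7 from -0.30 to -0.10, Vwf from -0.35 to -0.0067, Cd79a from -0.48 to -0.13 and Camp from -0.40 to -0.15. Among genes in the upper 50% of mean level, B cell (mean -0.17), T cell (-0.19), granulocyte (-0.18) and dendritic cell markers (-0.16) passed as lower, and inhibitors of cytokine signalling (0.35) as higher, while the calls of pattern recognition (0.27), costimulation (0.19) and macrophage identity genes (-0.04) ended. Cytokines stood at 0.66 and early transcription factors at 0.41 there, both with the call kept.

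The spike-in and sense-strand controls differed between the letters by -0.92 and 0.63 (B minus A) and between the groups by 0.58 and -0.22 (infected minus mock). The spike-in controls averaged 8.21 in mock A, 6.93 in mock B, 8.43 in infected A and 7.86 in infected B. Sense-strand controls averaged 6.41 and 6.48 in mock A and infected A, and 7.33 and 6.81 in mock B and infected B. The 3' minus 5' difference of the transferrin receptor controls was 2.04, 1.66, 2.03 and 1.88 in mock A, mock B, infected A and infected B, and those of Gapdh and Actb lay between -0.25 and 0.09. That of the pyruvate carboxylase controls was 0.26, 0.21, 0.30 and 0.28 in the same order, and the yeast controls averaged 3.60, 3.61, 3.50 and 3.55. For 18S ribosomal RNA the 3' minus 5' difference was -1.48, 0.22, -0.79 and 0.32 in that order, higher in both B arrays.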

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

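All settings in this part were planned before the data were examined. The letters share only a name in the labels, and their deviations from the group means correlated at 0.763 across probe sets. With the replicate letter as a block, calls went from 7 to 699, 540 higher and 159 lower, with all 7 still past. A further 18 named genes passed as higher, among them Ptgs2, Ccl2, Il1b, Nfkbia, Il6, Socs3 and Ccl5, while Ifit1 and Cxcl10 did not. The level of Il6 lay near that of the yeast controls. As lower, 5 named genes passed, C1qa, Cytip, Ahnak, C1qc and Ctla2b. The block leaves 1 residual degree of freedom. The list count was 14 with the block, which ended the call of the macrophage identity list (adjusted p = 0.0851).

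Cyclic loess gave 3 calls, all higher, a further quantile normalization 0 and an adjusted p under 0.01 gave 0. At least 2-fold with separated arrays and no p-value gave 50, 48 higher and 2 lower. Leaving out each array gave 0 to 8 calls, all higher, the lone array being assumed to vary like the other group. Dim probe set filters, array medians, variance priors, the 2-fold minimum and suffix-free probe sets gave 5 to 7. Lists past the threshold went from 15 (12 higher, 3 lower) to 0 (0 and 0) with an estimated inter-gene correlation and to 0 (0 and 0) with fry, and lower lists to 1 with cyclic loess. Other settings called 10 to 16 lists. The cause was not tested for any of these.

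Of 55 named genes 5 changed sign, all uncalled. Leaving out each array gave -0.044 to 0.20 for Il12b, -0.058 to 0.12 for Actb (-0.020 with cyclic loess), -0.14 to 0.13 for Irf1, -0.19 to 0.018 for Nos2 and -0.29 to 0.090 for Ifnb1. The test's direction turned for 12 lists. Leaving out each array gave means of -0.083 to 0.085 for interferon-gamma targets, -0.074 to 0.12 for MHC class I, -0.052 to 0.14 for apoptosis, -0.16 to 0.16 for lysosome, -0.064 to 0.31 for cholesterol, -0.015 to 0.066 for lipid, -0.098 to 0.072 for S phase, -0.18 to 0.12 for mitosis, -0.087 to 0.087 for ribosomal, -0.17 to 0.030 for granulocyte, -0.22 to 0.0063 for fibroblast and -0.071 to 0.015 for erythroid and endothelial genes. Direction also turned with the replicate block (means 0.00088 for interferon-gamma targets, 0.023 for MHC class I, 0.025 for lipid), with the mean over a gene's probe sets (0.032 for MHC class I, 0.021 for lipid), with the upper 50% of genes (-0.021 for interferon-gamma targets, 0.0099 for apoptosis, 0.046 for cholesterol, 0.067 for lipid), with fry (0.023 for MHC class I, 0.025 for lipid, 0.00027 for ribosomal) and with rank-based camera (0.043 for apoptosis). Where the mean is the one in the report, only the test's direction turned. The cause was not tested.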

Other observations

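The tests of the letter difference and of macrophage markers in general were chosen after the result was seen, and the tests of brightness and of background were written before it. Genes in the next paragraph were chosen after their values were seen, and none of them passed over all probe sets.

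Beyond the lists, transcripts with other roles were at least 2-fold higher with separated arrays. Plpp1, a lipid phosphatase, differed by 1.79 (SE 0.14, limma adjusted p = 0.059), and Pou2f2, a transcription factor, by 1.65. Slc11a2, an iron and metal ion transporter, differed by 1.33, the carboxypeptidase Cpd by 1.56 and the receptor gene Lilr4b by 1.31. Pou2f2 was higher by 1.65 in replicate A and by 1.65 in replicate B, and Slc11a2 by 1.21 and 1.45. In the type I interferon list Usp18 was at 0.80, Isg15 at 0.50 and Irf7 at 0.42, while in replicate B these were 0.47, 0.19 and 0.13.

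The 4 arrays split by letter more than by infection. Limma called 420 probe sets for B against A, 7 for infected against mock and 0 for the crossed split, so the arrays carry a structure that follows the letters, and the 3 splits are too few for a share under 0.05. Probe sets with the r suffix, a class set by the choice of probes, lay lower in B than those without a suffix. The difference of medians was -0.174 (95% bootstrap interval over probe sets -0.199 to -0.145). Probe sets were resampled and arrays were not, so the interval does not measure the spread between arrays of a letter. The r suffix class made up 40 of the 54 probe sets at least 2-fold lower in B and 1 of the 56 at least 2-fold higher. The same class had a median of -0.0728 in infected minus mock arrays, against 0.00014 without a suffix, so it also lay lower in infected arrays, and the letter value is consistent with, but not specific to, a difference in hybridisation or labelling for part of the split. Loss of RNA 5' ends in one letter stays open, since 2 of 4 control transcripts separated the letters in one direction, with a lower 3' minus 5' difference in B, while 18S ribosomal RNA separated them in the other (-1.48 and -0.79 in A, 0.22 and 0.32 in B), and a difference between the cultures was not tested.

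All 3 subunit genes of complement C1q were lower in both letters, with differences in A and B of -1.28 and -1.33 for C1qa, -0.48 and -0.63 for C1qb and -0.73 and -0.88 for C1qc, though a second, dimmer C1qb probe set gave -0.02. The 2897 other probe sets of that brightness had a median change of 0.0212 (95% bootstrap interval over probe sets 0.0148 to 0.0277). The normalised values thus held no fall shared by probe sets of that brightness. RMA makes the arrays' distributions alike, which draws such a median towards 0, so this test cannot decide on a shift before normalization. A general fall of macrophage markers was tested on the 19 other identity genes. Their median was -0.0500 (bootstrap interval over genes, not arrays, -0.143 to 0.173, SD of the changes 0.360), beside -0.81 for the C1q genes. The interval lies above the C1q change, which argues against a fall of that size in the other markers. The bound written for excluding a general fall was not met, so a smaller fall is not excluded. A response of C1q genes to infection may be a candidate explanation, and as a hypothesis it was found on these same arrays.

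Nos2, Il12b and Ifnb1 stayed near their mock level while Nfkbiz, Tnf and Cxcl2 rose. Probe sets that read only background could give this. All 3 of the genes lay above the brightest yeast control (3.87) in the infected mean, at 5.11, 6.14 and 5.19, which met the bound set in advance. That bound was too low, as a comparison added after the result was seen shows, because 40 markers of lymphoid, erythroid and endothelial cells had a median of 5.80 in the same arrays and 0 of the 3 genes lay above their 75th percentile of 6.86. Absence of a response and absence of a readable signal therefore cannot be told apart for these 3 genes.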
